A study of Mus musculus with 30 samples.

How the data were processed

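Single-cell RNA was measured in mouse lung 14 days after bleomycin, in 5 arms and 3 sort gates per arm, as 15 10x gene expression libraries with 15 matching hashtag libraries. The deposited matrices hold raw counts, UMIs per feature and cell barcode, which the authors made with Cell Ranger 6.0.1 and bcl2fastq against GRCm38. They apply no normalization, and they list cell-called barcodes only. The deposited barcode and feature files hold other content, the cell barcodes and the names of 52636 genes and 5 hashtags, and no measurement. The annotation release and the sequencing depth in reads are not given in the sources used here. Gene coordinates and exonic lengths were taken from GENCODE M21 on GRCm38, matched by Ensembl identifier.

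Each library's depth in total gene UMIs was, for PBS, isotype, anti-OSM, anti-IL6R and the combination in turn, 58865683, 35839547, 35778395, 64506863 and 56615274 in the CD45-positive gate. In the CD31/EpCAM gate it was 70170709, 58272635, 57575560, 68691732 and 55889140, and in the triple-negative gate 73264473, 53588608, 45710220, 67173336 and 79931211. Barcodes numbered, in the same order, 11218, 4276, 5888, 11079 and 11446, then 16117, 9688, 8554, 14745 and 9206, then 16340, 5209, 4849, 10524 and 12002. Tests used counts summed per hashtag subset and class: 405 to 2070 cells and 4031495 to 12715537 UMIs per subset for fibroblast-like, 38 to 659 and 348831 to 5584433 for AT2-like, 510 to 1285 and 1671787 to 3992199 for capillary endothelial-like, 30 to 350 and 342871 to 3945594 for monocyte-derived macrophage-like, and 86 to 605 and 325987 to 2290260 for T-like cells. Depth differed between the arms, so a thinned alternative was run.

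Barcodes with under 300 genes, under 500 UMIs or 15% or more mitochondrial UMIs were removed (4898). Hashtags were called with HTODemux of Seurat 5.3.0 (quantile 0.99), which gave 77.6 to 88.2% singlets, 5.11 to 19.4% cells with more than 1 hashtag and 0.102 to 13.8% with none; the last groups were left out. A pair of cells with the same hashtag in 1 droplet stays in the data, and no correction for free RNA was made. Each gate was clustered with scanpy 1.11.5 (2000 variable genes, 40 principal components, 15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2). Clusters were named from markers of 26 classes by the mean log2 fold of the detected markers (at least 3 in 20% of cells, score of at least 1.5, margin of at least 0.3). The reference for this score was changed after it was seen which clusters stayed unnamed and before any test between arms: 2 versions were tried, against the rest of the gate and against the median cluster of the 3 gates, and the latter was used. These thresholds, and the minimum of 100 cells for a class in the share tests, were set after the data had been seen. The 12 unnamed clusters, listed in the closing section, were not tested.

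The replicate was the hashtag subset, the cells of 1 hashtag in 1 library, with at least 20 cells of the class. As a check of what hashtags separate, the same hashtag number was compared across gates of an arm: subsets of fibroblast-like cells of 2 gates correlated at 0.352 to 0.619 after centring and each of 5 matched its own number best in every arm (lowest correlation of a pair 0.163). Other pairs of classes agreed less: T-like and capillary endothelial-like cells at means of 0.0287 to 0.0887, with 1 to 4 of 5 matched, and triple-negative fibroblast-like and capillary endothelial-like cells at 0.0468 to 0.235, with 2 to 5. Numbers were taken to pair only the fibroblast-like subsets, and tests between their gates were also run with a replicate block. Dispersion between hashtag subsets was 1.81 to 8.91 times that between random sets of cells. The labels do not name an animal per hashtag, so n is given as subsets.

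Genes were tested per class with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood F test, all 5 arms in 1 fit, Benjamini-Hochberg 0.05, prior count 2). The 6 comparisons were isotype against PBS, each antibody arm against isotype, and the combination against each single antibody. Lists of genes were tested with camera and fry of limma 3.58.1, with a preset correlation of 0.01 and an estimated one, adjusted over the lists of a class and comparison. Shares were compared with exact two-sided permutation tests over 252 arrangements, whose smallest p is 0.00794, in Python (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Comparisons, gene lists, markers, tests and the rule for named genes were chosen before the data were examined. That rule takes, per class and comparison, the 6 called genes in each direction with the largest fold change and a mean of at least 32 CPM, up to 4 members of each list of the class with the smallest p, and always Il6, Osm, Il6ra, Osmr, Il6st and Socs3; of these, a part is named here. Markers of other cells are named only as such. Genes alike in all 3 gates were singled out after their values were seen.

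The fit was tested on simulated data, negative binomial counts with each class's means, library sizes and dispersions and 200 genes changed between 2 arms: 2.31 to 6.33% of calls were false, and edgeR gave 0 calls between 2 unchanged arms. Alternatives planned were relative log expression normalization, DESeq2 1.42.0, no low-count filter, a stricter hashtag call (at least 10 hashtag UMIs and 5 times the second), a cell filter of 1000 genes and 10% mitochondrial UMIs for shares, Leiden resolution 2.0 for shares, fits of the 2 compared arms alone, leaving out each subset, estimated correlations and split isotype subsets. Alternatives added later are named in the closing section. Other splits of the 10 subsets of 2 arms were drawn (40 of 126) and refitted. Classes other than these 5 were not tested for genes, and the separate hashtag libraries were not used here because the gene expression matrices hold the hashtag counts.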

Results

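The study measured RNA in single cells of mouse lung 14 days after bleomycin, which injures the lung and leads to fibrosis, and asked what antibodies against oncostatin M (OSM) and the IL-6 receptor (IL6R), alone or together, change in the injured lung. OSM and IL-6 are related cytokines whose receptors share the subunit gp130, encoded by Il6st, and act through the transcription factor STAT3. There were 5 arms: saline (PBS) and bleomycin with isotype antibody, anti-OSM, anti-IL6R or both antibodies (the combination). Cells of each arm were sorted into 3 gates: CD45-positive leukocytes, cells positive for CD31 or EpCAM (endothelial and epithelial), and cells negative for all 3 markers (triple-negative, mostly mesenchymal). Each of the 15 gene expression libraries held cells with 5 hashtags, barcoded antibodies that mark pools of cells, and a second library per sort counted the hashtags, which makes 30 samples. The files held 151141 cell barcodes, 4276 to 16340 per library, with 35778395 to 79931211 gene UMIs (unique transcript counts) per library and a median of 3061 to 8903 UMIs per barcode. After filtering and removal of cells with no hashtag or more than 1, 121337 cells remained.

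Cells were grouped by expression and named from marker genes as "X-like", with 12 of 98 clusters left unnamed. Replicates are hashtag subsets: the cells of 1 class carrying 1 hashtag in 1 library (n = 5 per arm and class). The labels do not say that a hashtag marks an animal, so all p-values measure only the spread between hashtag subsets, which may be technical. Each arm of a gate is also a single 10x library, so arm and library cannot be told apart. In what follows, a gene rose or fell when it passed a 5% false discovery rate over all genes of its class (edgeR). Values in parentheses after a gene are log2 fold changes ± SE, the SE taken as the fold change divided by the root of the quasi-likelihood F statistic. Expression levels are CPM, counts scaled to library totals, mean ± SD over 5 subsets. Gene lists were tested as sets with camera, at a preset correlation between genes and again at an estimated one (estimated adjusted p).

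Bleomycin with isotype changed the cell composition of every gate relative to saline (exact two-sided permutation tests on hashtag subsets, n = 5 per arm, adjusted over the classes of a gate). In the CD31/EpCAM gate, AT2-like cells, which make surfactant, fell from 17.5 ± 4.48 to 5.94 ± 1.95% (SD; adjusted p = 0.0265, exact permutation test), and AT1-like cells, which line the alveolus, from 5.76 ± 0.906 to 1.24 ± 0.503%. Club-like airway cells rose from 0.854 ± 0.145 to 4.17 ± 1.11% and lymphatic endothelial-like cells from 0.728 ± 0.397 to 2.48 ± 1.26%. Among CD45-positive cells, alveolar macrophage-like cells fell from 7.45 ± 2.47 to 0.254 ± 0.15%, NK-like cells from 8.71 ± 1.85 to 3.48 ± 1.21%. Monocyte-like cells fell from 11.1 ± 4.05 to 3.45 ± 1.72% and mast or basophil-like cells from 0.525 ± 0.294 to 0.129 ± 0.148%. T-like cells rose from 13.2 ± 1.88 to 24.3 ± 3.36%, B-like cells from 32.4 ± 6.05 to 41.5 ± 3%, monocyte-derived macrophage-like cells from 4.85 ± 1.71 to 7.81 ± 0.979% and dendritic-like cells from 2.44 ± 0.885 to 4.38 ± 0.441%. In the triple-negative gate fibroblast-like cells fell by 11.1 percentage points and smooth muscle-like cells rose by 4.33. The 4 calls of that gate (adjusted p = 0.0417, exact permutation test) became 0 under either a stricter cell filter or a stricter hashtag call, though the fibroblast-like difference stayed at -10.1 and -11.1 points (adjusted p = 0.0556, exact permutation test). Shares are within a gate, set by the sort, and unnamed cluster 7 of CD31/EpCAM went from 0.265 to 9.39%. With PBS the monocyte-derived macrophage-like class had another main cluster and higher resident macrophage genes, so its rise may not be of monocyte-derived cells.

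The share tests called 12 differences with anti-IL6R against isotype and 0 with anti-OSM or the combination. With anti-IL6R, alveolar macrophage-like cells made up 2.02 ± 0.525% of CD45-positive cells against 0.254 ± 0.15% with isotype (adjusted p = 0.0175, exact permutation test). Monocyte-derived macrophage-like cells rose from 7.81 ± 0.979 to 13.3 ± 1.81%, dendritic-like cells from 4.38 ± 0.441 to 7.51 ± 1.05% and NK-like cells from 3.48 ± 1.21 to 6.13 ± 1.36%, while B-like cells fell from 41.5 ± 3 to 28.4 ± 4.99%. In the CD31/EpCAM gate club-like cells fell from 4.17 ± 1.11 to 1.19 ± 0.471% and ciliated-like cells from 3.47 ± 3.17 to 1.07 ± 0.366%. Without isotype HTO2 (9.10%) the latter call was lost (adjusted p = 0.0529, exact permutation test). Fibroblast-like cells, which the sort should exclude, rose from 17.8 ± 3.13 to 39.2 ± 7.36%. In the triple-negative gate fibroblast-like cells rose from 69.4 ± 4.15 to 80.7 ± 3.93%, and smooth muscle-like, mesothelial-like and neutrophil-like cells fell, with differences of -4.28, -1.88 and -0.429 points. The neutrophil-like call was lost with the stricter hashtag call (adjusted p = 0.0694, exact permutation test). With anti-OSM, 4 classes had an unadjusted p under 0.05 (combination: 3). They included monocyte-derived macrophage-like cells, 4.54 ± 0.619% against 7.81 ± 0.979% with isotype. Their adjusted p = 0.0873 (exact permutation test) is the lowest here for a class separated alone, so the 0 calls leave change open.

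**Figure D1:**
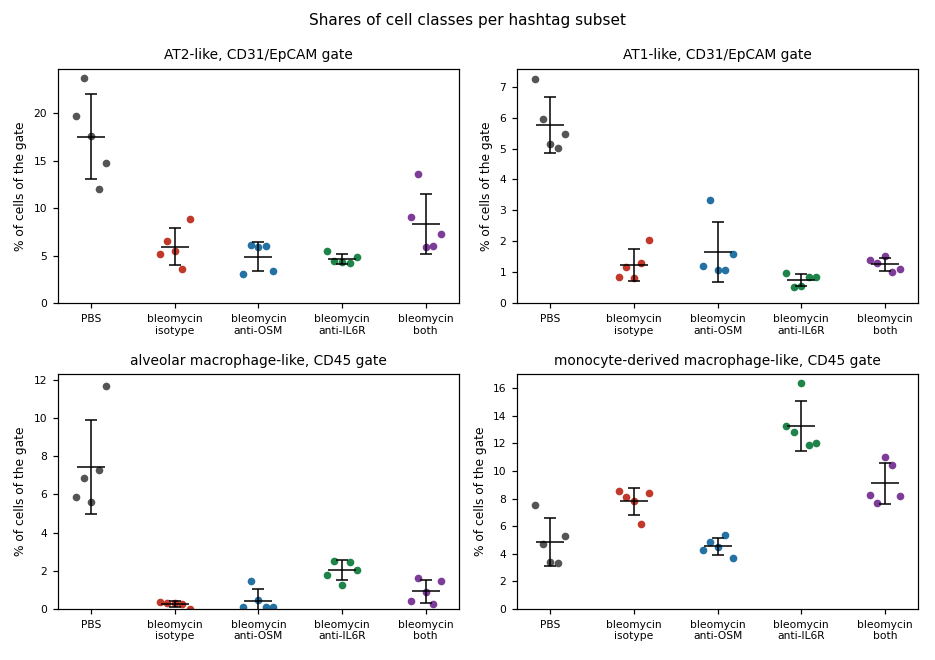
Each point is the share of a cell class in 1 hashtag subset (y axis, percent of singlet cells of the gate), by arm on the x axis, with mean and SD over 5 subsets. AT2-like and AT1-like cells were lower with bleomycin and isotype than with PBS (5.94 against 17.5% and 1.24 against 5.76%), and alveolar macrophage-like cells stood at 0.254% with isotype and 2.02% with anti-IL6R.

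Gene tests covered 5 classes. Bleomycin with isotype against PBS called 6051 of 14933 genes tested in fibroblast-like, 3438 of 8659 in AT2-like, 2810 of 11436 in capillary endothelial-like, 2681 of 9095 in monocyte-derived macrophage-like and 2013 of 9972 in T-like cells. In the same order anti-IL6R against isotype called 2919, 1170, 2718, 435 and 473. Anti-OSM called 1257, 52, 252, 61 and 124, and the combination 1023, 1458, 1943, 173 and 449. The combination differed from anti-OSM in 1260, 445, 1399, 347 and 393 genes, and from anti-IL6R in 59, 33, 194, 30 and 44.

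**Figure D2:**
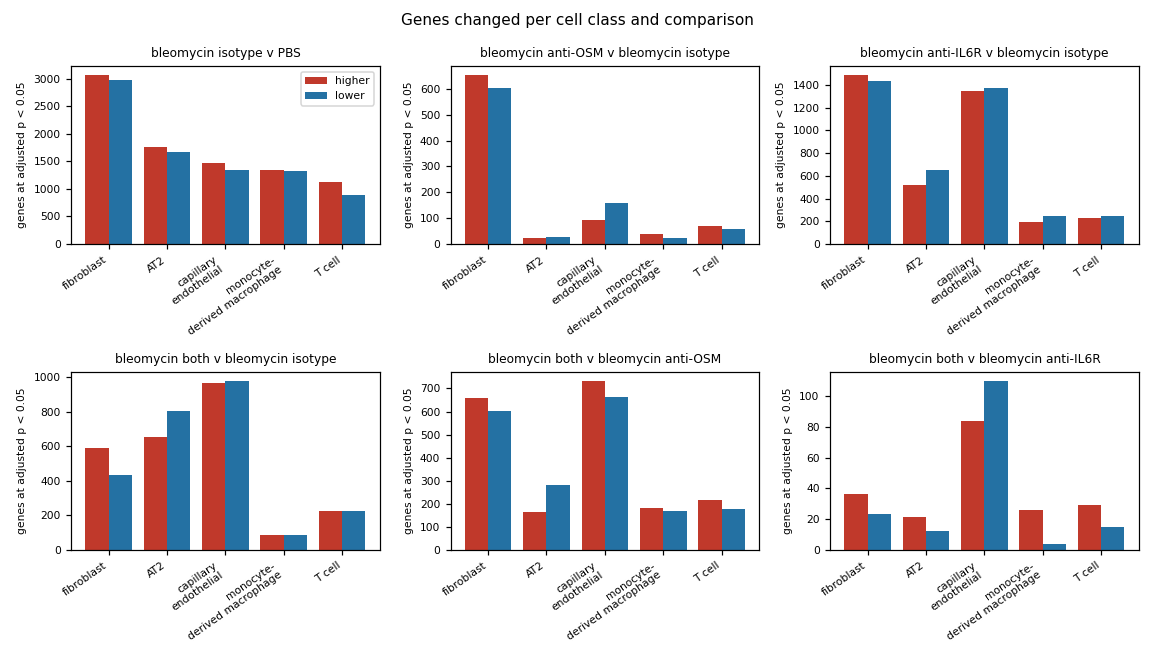
Bars give the number of genes higher (up) or lower (down) in the first arm of each comparison, past a 5% false discovery rate, for the 5 classes, 1 panel per comparison. In fibroblast-like cells bleomycin with isotype against PBS gave 3073 higher and 2978 lower, and the combination against anti-IL6R gave 59 in all.

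In fibroblast-like cells bleomycin with isotype raised genes of scar-forming and contractile fibroblasts and lowered genes of resting alveolar fibroblasts. Spp1, which encodes osteopontin, rose from 7.27 ± 5.27 to 2790 ± 1705 CPM (8.59 ± 1.14, adjusted p = 3.72e-06), and Cthrc1, a marker of collagen-producing fibroblasts in fibrosis, from 4.18 ± 1.73 to 185 ± 92.7 CPM (5.48 ± 0.75). Acta2, smooth muscle actin, rose from 87.9 ± 33.6 to 777 ± 456 CPM (3.14 ± 0.45, adjusted p = 9.43e-06). Among matrix and fibrosis genes 20 of 24 rose and 0 fell (20 and 0 adjusted over the list alone; camera adjusted p = 8.49e-12, estimated adjusted p = 0.297). They included Tnc, the matrix protein tenascin (4.20 ± 0.34), Ltbp2, which binds elastic fibres (3.41 ± 0.30) and Runx1, a transcription factor (1.40 ± 0.15). Of 10 contractile genes 8 rose, and 8 adjusted over the list alone (camera adjusted p = 8.53e-05, estimated adjusted p = 0.297), with Tagln at 3.36 ± 0.48 and Tpm1, tropomyosin, at 1.68 ± 0.18. Proliferation genes rose too, 16 of 18 (16 adjusted over the list alone; camera adjusted p = 1.08e-07, estimated adjusted p = 0.297). Interferon-stimulated genes rose in 15 of 20 cases and fell in 2 (16 and 2 adjusted over the list alone; camera adjusted p = 3.23e-05, estimated adjusted p = 0.336), Isg15 by 1.41 ± 0.19. The acute-phase genes Lcn2, Lrg1 and Hp, secreted in inflammation, rose by 5.01 ± 0.93, 5.71 ± 0.69 and 3.37 ± 0.48, and Timp1, a metalloproteinase inhibitor, by 2.22 ± 0.29.

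Alveolar fibroblast identity genes fell: 10 of 13 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 4.81e-04, estimated adjusted p = 0.297). Inmt, a methyltransferase of lung fibroblasts, fell from 2668 ± 666 to 523 ± 230.3 CPM (-2.35 ± 0.40) and the fibroblast transcription factor Tcf21 by -1.08 ± 0.19. Of the 11 pathway ligands and receptors 2 rose and 4 fell (camera adjusted p = 0.486). Il6 fell from 474 ± 46.6 to 255 ± 44.6 CPM (-0.90 ± 0.16, adjusted p = 1.01e-04), and Il6ra by -1.15 ± 0.19. The fold changes of Osmr (-0.20 ± 0.10, adjusted p = 0.11) and Il6st (-0.10 ± 0.08, adjusted p = 0.348) did not pass. Socs3, a feedback inhibitor induced by STAT3, fell from 701 ± 25.7 to 304 ± 96.3 CPM (-1.2 ± 0.24). The gp130-STAT3 responsive genes went both ways (7 up and 5 down of 20, 8 and 5 adjusted over the list alone, camera adjusted p = 0.661, with a median of -0.08 against a test direction of up). Inflammatory fibroblast genes (7 up, 3 down of 16) and stress genes (5 up, 8 down of 16) also went both ways. Markers of other cells moved in the same cells: of 3 macrophage transcripts 2 rose and 1 fell, and 2 of 2 endothelial, 1 of 2 AT2 and 1 of 3 club and ciliated ones fell. In fibroblast-like cells of the CD31/EpCAM gate, other libraries of the same arms, Il6 changed by -0.31 (adjusted p = 0.146) and its call was lost. A cluster with Spp1, Tnc and Tagln among its top genes held 0.0203% of the class with PBS and 10.4% with isotype, and 2.74% with anti-OSM, 3.43% with anti-IL6R and 7.60% with the combination. Class means may therefore follow the mix of clusters rather than changes per cell.

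With anti-OSM, fibroblast-like cells of the bleomycin lung had lower Spp1, Tnc and Tpm1 and higher C3 and Il6 than with isotype. Spp1 fell from 2790 ± 1705 to 275 ± 353 CPM (-3.34 ± 0.87, adjusted p = 0.0181) and Tnc from 337 ± 76.2 to 124 ± 61.4 CPM (-1.43 ± 0.30, adjusted p = 0.00496). Of 10 contractile genes 3 fell (9 adjusted over the list alone; camera adjusted p = 9.42e-05, estimated adjusted p = 0.446), with Tpm1 at -0.80 ± 0.17 and Cald1, which binds actin, at -0.55 ± 0.13. Of 24 matrix genes 5 fell and 1 rose (camera adjusted p = 0.435, median 0.00), with Col12a1, a fibril-associated collagen, at -0.87 ± 0.22. Il11, a gp130 cytokine of activated fibroblasts (-1.25 ± 0.32), the EGF-receptor ligand Ereg (-1.56 ± 0.32), the protease inhibitor Serpine2 (-1.42 ± 0.24) and the signalling regulator Rgs2 (-1.47 ± 0.22) fell as well. In the other direction, 5 of 16 inflammatory fibroblast genes rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0127, estimated adjusted p = 0.446). They included complement C3 (0.91 ± 0.17, adjusted p = 0.00219) and the alarmin Il33 (0.80 ± 0.16). Il6 rose from 255 ± 44.6 to 398 ± 82.7 CPM (0.65 ± 0.16, adjusted p = 0.0138).

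Socs3 stood at 402 ± 179 CPM against 304 ± 96.3 with isotype (0.40 ± 0.24, adjusted p = 0.33), and 1 of 20 gp130-STAT3 responsive genes rose and 0 fell (camera adjusted p = 0.212). No member of the proliferation list passed (camera adjusted p = 0.00274 downward, estimated adjusted p = 0.603). Neither did any of the interferon list (camera adjusted p = 0.799) or the stress list (camera adjusted p = 0.0186 upward, estimated adjusted p = 0.591). Alveolar identity genes gave 2 up and 1 down (camera adjusted p = 0.977). Scgb1a1, an airway cell transcript, fell beside these genes (-3.39 ± 0.75). The count of 1257 rested on single subsets: it was 702 without isotype HTO4, 815 without isotype HTO2 and 805 without anti-OSM HTO3, and 243 when only the 2 arms were fitted, where Spp1 (adjusted p = 0.0849), Tnc (0.0639) and Il6 (0.057) were not called. Leaving out isotype HTO2 ended the call of Col12a1 (adjusted p = 0.0558), and leaving out anti-OSM HTO3 or isotype HTO1 that of Il11 (highest adjusted p = 0.0687). In fibroblast-like cells of the CD31/EpCAM gate 250 genes were called, of which 66 were among the 1257. Fitted together, the 2 gates shared 78 called genes (31.1 for independent lists), only 42 of them in the same direction. There Spp1 (-1.03), Tnc (-0.19), C3 (0.13) and Il6 (0.25) were not called, and Tpm1 (0.04), Col12a1 (0.06), Il11 (0.87) and Ereg (0.34) had the other sign.

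Anti-IL6R lowered contractile and proliferation genes in fibroblast-like cells. Acta2 fell from 777 ± 456 to 213 ± 111 CPM (-1.87 ± 0.43, adjusted p = 0.00407). Timp1 fell from 1307 ± 735 to 565 ± 88.5 (-1.21 ± 0.28, adjusted p = 0.00488) and Lcn2 from 66.8 ± 89.4 to 8.54 ± 3.62 (-2.97 ± 0.77, adjusted p = 0.00932). Contractile genes fell in 8 of 10 cases (10 adjusted over the list alone; camera adjusted p = 1.03e-05, estimated adjusted p = 0.398). Tagln stood at -1.97 ± 0.46, Actg2 at -2.62 ± 0.57 and Tpm1 at -0.96 ± 0.17. Proliferation genes fell in 13 of 18 (15 adjusted over the list alone; camera adjusted p = 5.33e-06, estimated adjusted p = 0.623), among them Ccnb2, a mitotic cyclin (-1.56 ± 0.35), and Mki67 (-1.97 ± 0.47). Of 24 matrix genes 6 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.114), such as Ltbp2 (-1.0 ± 0.26), Tnc (-1.07 ± 0.30) and Col12a1 (-0.91 ± 0.21). Kif26b (-2.14 ± 0.50) and Runx1 (-0.59 ± 0.15) fell too. Spp1 (-2.71 ± 0.84) and Cthrc1 (-1.84 ± 0.58) fell, calls lost in 5 and 6 of 10 leave-one-out fits (highest adjusted p = 0.063 and 0.0762), and the call of Lcn2 was lost without isotype HTO2 (adjusted p = 0.0867).

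Rising genes included Zbtb16, a glucocorticoid-induced repressor (1.30 ± 0.24), Herpud1 and Sdf2l1 of the endoplasmic reticulum stress response (1.54 ± 0.18 and 1.26 ± 0.22). Others were C3 (0.84 ± 0.17) and Il6, from 255 ± 44.6 to 438 ± 88.9 CPM (0.78 ± 0.16, adjusted p = 0.00176). Il6ra, the antibody target's own gene, rose by 0.57 ± 0.19, a call lost in 6 of 10 leave-one-out fits, highest adjusted p = 0.139. Socs3 did not pass (0.57 ± 0.24, adjusted p = 0.092). The gp130-STAT3 responsive genes went both ways (3 up, 3 down; camera adjusted p = 0.333), as did inflammatory genes (4 up, 3 down; camera adjusted p = 0.72). Stress genes rose in 5 of 16 (8 adjusted over the list alone; camera adjusted p = 0.0472, estimated adjusted p = 0.846). Neutrophil transcripts, which fibroblasts do not make, moved down beside these groups (S100a9 -2.56 ± 0.43; camera adjusted p = 0.0454, estimated adjusted p = 0.35). Fibroblast-like cells of the triple-negative and CD31/EpCAM gates shared 1195 called genes, 1079 in the same direction. Acta2, Tagln, Timp1, Lcn2, Kif26b, Ccnb2, C3 and Il6 kept their calls in the CD31/EpCAM gate, while Ltbp2 (-0.22), Col12a1 (-0.06), Runx1 (-0.12), Actg2 (-0.28), Mki67 (-0.17) and Sdf2l1 (0.46) did not and Tnc was at 0.06.

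The combination changed fewer fibroblast genes than anti-IL6R alone (1023 against 2919), and Acta2, at 373 ± 129.9 CPM, did not pass (-1.06 ± 0.42, adjusted p = 0.121). It raised Zbtb16 from 51.1 ± 20.1 to 156 ± 21.6 CPM (1.61 ± 0.24, adjusted p = 2.65e-04), the glucocorticoid-induced Tsc22d3 (1.25 ± 0.14) and Sdf2l1 (1.38 ± 0.22). It lowered the cold-induced RNA-binding protein Rbm3 (-1.10 ± 0.25) and Inhba, which encodes an activin subunit (-0.93 ± 0.25, lost in 5 of 10 leave-one-out fits, highest adjusted p = 0.0907). No contractile gene passed over all genes and 6 fell adjusted over the list alone (camera adjusted p = 0.011, estimated adjusted p = 0.627). Proliferation genes gave 1 faller and 9 adjusted over the list alone (camera adjusted p = 0.002, estimated adjusted p = 0.627). Stress genes rose in 2 of 16, and alveolar identity genes moved up with none passing (camera adjusted p = 0.0213 and 0.0431, estimated adjusted p = 0.627 for each). The count of 1023 was 627 without combination HTO3. Against anti-OSM, the combination had higher Zbtb16 (1.94 ± 0.25), Rgs2 (1.77 ± 0.22) and Serpine2 (1.21 ± 0.24; -0.35 in the CD31/EpCAM gate) and lower complement factor Cfb (-1.21 ± 0.15), with 1 of 2 neutrophil transcripts lower (camera adjusted p = 0.0281, estimated adjusted p = 0.125). Its count of 1260 was 797 without anti-OSM HTO3 and 816 without combination HTO5. Against anti-IL6R, Serpine2 (1.05 ± 0.24) and Nrcam (0.87 ± 0.20) were higher. That count of 59 was 6, 8, 13, 22, 31, 10 and 15 without anti-IL6R HTO4, HTO2 or HTO5 or combination HTO1, HTO3, HTO4 or HTO5. The matrix, contractile and proliferation lists moved up with no gene passing (camera adjusted p = 7.17e-04, 7.17e-04 and 0.00528, lowest estimated adjusted p = 0.619). Both genes were lost in 7 and 8 of 10 leave-one-out fits (highest adjusted p = 0.182 and 0.17).

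**Figure D3:**
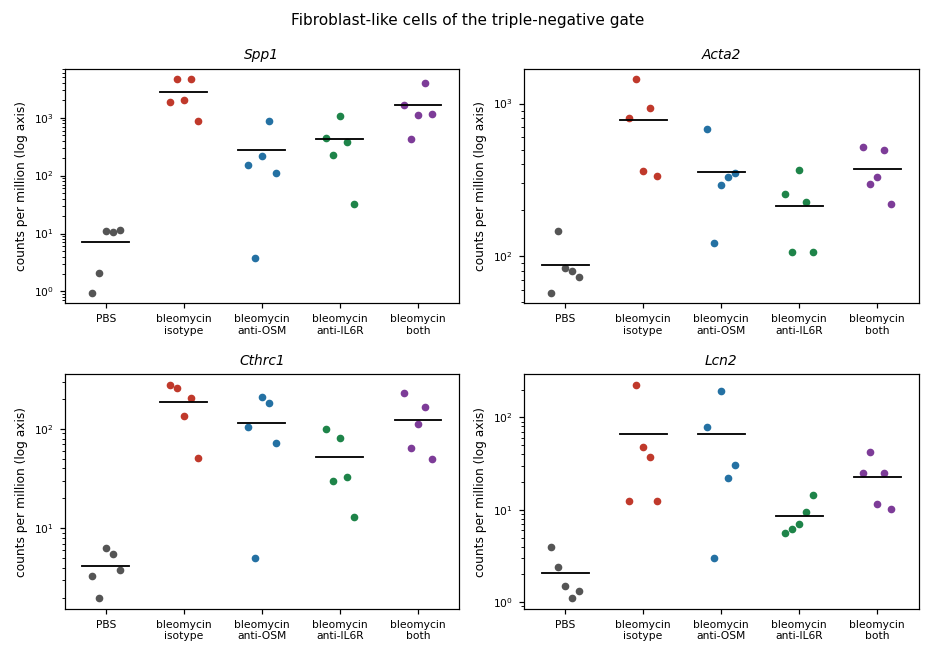
Points are the expression of Spp1, Acta2, Cthrc1 and Lcn2 in fibroblast-like cells (y axis, CPM on a log axis) of each of 5 hashtag subsets per arm (x axis), and lines the means. Mean Spp1 was 7.27 CPM with PBS, 2790 with isotype, 275 with anti-OSM and 427 with anti-IL6R.

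In AT2-like cells bleomycin with isotype raised genes of the transitional state between AT2 and AT1 cells and of cell division. Sprr1a, a squamous differentiation gene, rose from 6.27 ± 6.73 to 307 ± 363 CPM (5.58 ± 0.87, adjusted p = 8.89e-06). Lcn2 rose from 833 ± 183 to 5769 ± 1241 (2.79 ± 0.30, adjusted p = 2.67e-08) and the calcium-binding S100a6 from 192 ± 56.2 to 1521 ± 871 (2.98 ± 0.50). Without clusters of few UMIs, which held 39.5% of the isotype arm's AT2-like cells, Sprr1a (0.74) and S100a6 (0.19) were not called. Transitional epithelial genes rose in 8 of 12 (9 adjusted over the list alone; camera adjusted p = 4.16e-04, estimated adjusted p = 0.354). They included the keratin Krt7 (2.14 ± 0.30) and the cell cycle inhibitor Cdkn1a (1.51 ± 0.22). AT1 genes rose in 6 of 10 (camera adjusted p = 0.00324, estimated adjusted p = 0.354), Pdpn by 3.35 ± 0.36 and Ager by 1.06 ± 0.13. Proliferation genes rose in 15 of 17 (camera adjusted p = 1.35e-04, estimated adjusted p = 0.354). AT2 identity genes went both ways (3 up, 7 down of 17; camera adjusted p = 0.198). The transcription factor Etv5 fell (-0.82 ± 0.16), as did lysozyme, Lyz2 (-0.99 ± 0.18), while Napsa, which processes surfactant protein, rose (0.56 ± 0.11). Of 6 pathway ligands and receptors 4 fell (camera adjusted p = 0.0175, estimated adjusted p = 0.145). Il6st fell from 88 ± 4.88 to 38.1 ± 5.51 CPM (-1.2 ± 0.13, adjusted p = 4.02e-08), Osmr from 117 ± 25.9 to 56.8 ± 4.62 (-1.02 ± 0.18) and Lifr by -1.2 ± 0.21. Socs3 fell from 241 ± 51.8 to 90.7 ± 22.6 CPM (-1.42 ± 0.18), and gp130-STAT3 responsive genes went 3 up and 8 down of 17 (camera adjusted p = 0.162). Stress genes fell in 9 and rose in 2 of 16 (camera adjusted p = 0.00677, estimated adjusted p = 0.354), and interferon genes rose in 4 of 8 (camera adjusted p = 0.0513). Endothelial transcripts fell in the same cells (4 of 4; camera adjusted p = 0.038, estimated adjusted p = 0.354).

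Anti-OSM called 52 genes in AT2-like cells, against 1029 at an unadjusted p under 0.05. The 52 became 16 with only the 2 arms fitted, 112 with DESeq2, 224 with no low-count filter and 90 under another naming of clusters. Pon1 rose from 1.55 ± 0.994 to 18.6 ± 17 CPM (3.80 ± 0.72, adjusted p = 0.00342; lost in 1 of 10 leave-one-out fits, highest adjusted p = 0.0708), as did the kinase Camk1d (0.96 ± 0.14). Rpl35 fell (-1.21 ± 0.14). Stress genes gave 1 riser of 16 (3 adjusted over the list alone; camera adjusted p = 4.95e-05, estimated adjusted p = 0.41).
With anti-IL6R, Il6st rose from 38.1 ± 5.51 to 75.1 ± 11.6 CPM (0.97 ± 0.14, adjusted p = 1.79e-05) and Lamp3 by 0.38 ± 0.09. Sprr1a fell from 307 ± 363 to 13.4 ± 6.32 CPM (-4.44 ± 0.94), S100a6 from 1521 ± 871 to 326 ± 123 (-2.21 ± 0.49) and Hopx, an AT1 gene, by -1.62 ± 0.43. Without clusters of few UMIs none of these 3 was called (-0.36, -0.62 and -0.89), while Il6st was (0.86). Those clusters held 11.1% of the class with anti-IL6R and 15.6% with the combination, so class means may follow the mix of clusters. Of 12 transitional genes 3 fell and 1 rose (camera adjusted p = 0.332), of AT1 genes 2 fell (camera adjusted p = 0.328). Of AT2 identity genes 2 rose (camera adjusted p = 0.0442, estimated adjusted p = 0.82). Fibroblast transcripts rose in the same cells (3 of 4; camera adjusted p = 0.00617, estimated adjusted p = 0.666), Col1a1 by 1.81 ± 0.46.
The combination also raised Il6st (0.92 ± 0.14), Zbtb16 (2.37 ± 0.29) and Hsp90aa1 (0.75 ± 0.11) and lowered Sprr1a (-3.32 ± 0.79), Hopx (-1.75 ± 0.42) and Cirbp, a cold-induced RNA-binding protein (-1.37 ± 0.30). Without clusters of few UMIs Sprr1a was at 1.49 in the combination. The combination's count of 1458 was 821 without combination HTO2. Its count against anti-OSM, 445, was 68 with only the 2 arms fitted, 129 under another naming of clusters, 285 without combination HTO2, 291 without anti-OSM HTO5 and 864 without anti-OSM HTO2. Of AT1 genes 2 were lower there (camera adjusted p = 0.0258, estimated adjusted p = 0.91). Against anti-IL6R, 3 of 4 fibroblast transcripts were lower in the combination (camera adjusted p = 1.29e-08, adjusted p = 0.0242 with an estimated correlation).

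Capillary endothelial-like cells after bleomycin with isotype expressed more activated endothelial and gp130-STAT3 responsive genes. Lrg1, an angiogenic glycoprotein, rose from 67.2 ± 32.8 to 885 ± 311 CPM (3.72 ± 0.40, adjusted p = 8.05e-08) and the collagens Col4a1 and Col4a2 by 1.45 ± 0.15 and 1.44 ± 0.14. Activated endothelial genes rose in 10 of 15 and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 2.09e-06, estimated adjusted p = 0.0693). Of 18 gp130-STAT3 responsive genes 9 rose and 1 fell (camera adjusted p = 1.13e-04, estimated adjusted p = 0.147). Timp1 rose (2.20 ± 0.31), while Socs3 did not pass (0.18 ± 0.12, adjusted p = 0.308). Proliferation genes rose in 16 of 18 (camera adjusted p = 2.56e-05, estimated adjusted p = 0.364). Interferon genes fell in 10 of 19 (11 adjusted over the list alone; camera adjusted p = 9.02e-04, estimated adjusted p = 0.398). Isg15 was at -0.95 ± 0.18, opposite to its rise in fibroblast-like cells, a difference that was not tested. General capillary genes fell in 7 and rose in 1 of 12 (camera adjusted p = 0.0129, estimated adjusted p = 0.318). Aerocyte genes fell in 3 of 11 (camera adjusted p = 0.344), and under another naming of clusters Car4 (0.38), Emp2 (0.38), Fibin (0.21) and Kdr (0.44) had the other sign. The natriuretic peptide receptor Npr3 fell from 239 ± 70.6 to 44.6 ± 12.9 CPM (-2.41 ± 0.26). AT2 transcripts fell in these cells in 4 of 4, a call that held with an estimated correlation (camera adjusted p = 2.03e-12 and 2.24e-04). Cluster 1 of the gate held 1.80% of the class with PBS and 47.6% with isotype.

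With anti-IL6R, Npr3 rose from 44.6 ± 12.9 to 214 ± 68.4 CPM (2.24 ± 0.26, adjusted p = 2.01e-07). So did Camk1d (2.24 ± 0.07), the chaperone Hsp90aa1 (1.5 ± 0.18) and the endothelial receptor Cd93 (0.56 ± 0.08). Lrg1 fell (-0.99 ± 0.35; lost in 7 of 10 leave-one-out fits, highest adjusted p = 0.105), as did the immediate-early gene Ier2 (-0.44 ± 0.12), Rpl35 (-2.04 ± 0.08) and Rpl38 (-1.92 ± 0.07). No list of endothelial genes was called. Fibroblast and AT2 transcripts, from other cells, rose beside them (4 of 4 and 4 of 4; estimated adjusted p = 0.00769 and 0.0156), Col1a1 by 3.13 ± 0.26 and Sftpc by 0.93 ± 0.09.
With anti-OSM the 252 called genes (154 with only the 2 arms fitted) included Rnaset2a (1.04 ± 0.13) and Camk1d (0.86 ± 0.07) upward and mt-Nd3 (-1.77 ± 0.09) and Ccdc85b (-1.56 ± 0.08) downward, with no endothelial list called. Fibroblast transcripts rose in 4 of 4 (estimated adjusted p = 0.0127), AT2 transcripts fell in 2 (estimated adjusted p = 0.0169). Club and ciliated ones fell in 2 (camera adjusted p = 0.00248, estimated adjusted p = 0.0844).
The combination raised Zbtb16 (1.73 ± 0.29), Npr3 (1.70 ± 0.26), Hsp90aa1 (1.40 ± 0.18) and Cd93 (0.46 ± 0.08). It lowered Cirbp (-2.09 ± 0.27) and S100a6 (-1.34 ± 0.26), beside a rise of 4 AT2 transcripts (estimated adjusted p = 0.00395), 3 fibroblast ones (camera adjusted p = 0.0372, estimated adjusted p = 0.452) and 2 erythroid ones. Against anti-OSM it had lower Fos (-0.83 ± 0.13) and Ier2 (-0.61 ± 0.12), with stress genes falling in 6 of 16 (camera adjusted p = 0.0339, estimated adjusted p = 0.964). It had higher Prx (0.54 ± 0.12) beside 4 AT2 transcripts (estimated adjusted p = 2.25e-04). Against anti-IL6R all 4 fibroblast transcripts were lower (estimated adjusted p = 1.76e-04).

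Monocyte-derived macrophage-like cells had higher lipid-associated and lower resident genes after bleomycin with isotype. Spp1 rose from 54.8 ± 35.1 to 4678 ± 3419.6 CPM (6.35 ± 0.53, adjusted p = 9.96e-10) and Lyve1, a marker of resident interstitial macrophages, fell from 254 ± 86.8 to 8.21 ± 4.61 (-4.93 ± 0.59, adjusted p = 4.43e-07). Lipid-associated and profibrotic genes rose in 14 of 18 and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 2.87e-08), and the call held with an estimated correlation (adjusted p = 0.0273). They included the fatty acid carrier Fabp5 (4.17 ± 0.34) and fibronectin, Fn1 (4.08 ± 0.44). Resident genes fell in 10 of 12 (camera adjusted p = 8.87e-08, estimated adjusted p = 0.142). The scavenger receptor Cd163 was at -3.65 ± 0.58 and the folate receptor Folr2 at -3.56 ± 0.42. Osm itself rose from 39.6 ± 19.5 to 191 ± 57.9 CPM (2.26 ± 0.32, adjusted p = 4.40e-06). Socs3 fell from 500.2 ± 79.8 to 188 ± 26.5 (-1.40 ± 0.18), Stat3 by -0.81 ± 0.15, Il6ra by -0.73 ± 0.14 and Il6st by -0.81 ± 0.17. The gp130-STAT3 responsive genes went 4 up and 8 down of 14 (camera adjusted p = 0.125), and pathway ligands and receptors 1 up and 3 down of 6. Inflammatory cytokine genes went both ways (4 up, 6 down of 13; camera adjusted p = 0.584), with the prostaglandin synthase Ptgs2 up (2.31 ± 0.41) and the chemokine Ccl7 (-2.14 ± 0.43) down. Interferon genes rose in 7 and fell in 1 of 18 (camera adjusted p = 0.0116, estimated adjusted p = 0.515), and MHC class II genes passed in 0 of 9 cases. Stress genes fell in 11 and rose in 2 of 16 (camera adjusted p = 1.94e-05, estimated adjusted p = 0.142). Club and ciliated transcripts fell in 2 of 2 and neutrophil ones in 1 of 2 (camera adjusted p = 0.125 and 0.356). Cluster 8 of the gate held 85.4% of the class with PBS and cluster 10 held 52.1% with isotype, so the class may hold other cells rather than changed ones.

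In the same class anti-OSM called 61 genes, with Osm itself at 139 ± 74.2 CPM against 191 ± 57.9 (-0.41 ± 0.27, adjusted p = 0.525). The lipase Lpl fell from 814 ± 212 to 363 ± 82.1 CPM (-1.16 ± 0.23; lost in 3 of 10 leave-one-out fits, highest adjusted p = 0.058). The stress factor Atf3 rose (0.98 ± 0.15) with 4 of 16 stress genes (8 adjusted over the list alone; camera adjusted p = 7.15e-07, estimated adjusted p = 0.16). MHC class II genes gave 1 riser, Cd74 (0.70 ± 0.16; lost in 7 of 10 leave-one-out fits, highest adjusted p = 0.109), and 4 adjusted over the list alone (camera adjusted p = 7.14e-04, estimated adjusted p = 0.382). The count of 61 was 13, 34 and 102 without anti-OSM HTO2, HTO4 and HTO1, and 25, 15, 18 and 21 without isotype HTO1, HTO2, HTO3 and HTO4, and 1 when only the 2 arms were fitted.
Anti-IL6R lowered Lrg1 (-4.56 ± 0.66, adjusted p = 4.26e-05), the growth factor Nrg1 (-2.07 ± 0.33), the glycolytic enzyme Eno1 (-1.64 ± 0.15) and arginase, Arg1, from 109.5 ± 169 to 8.08 ± 3.43 CPM (-3.70 ± 1.0; lost in 6 of 10 leave-one-out fits, highest adjusted p = 0.339). Of 14 gp130-STAT3 responsive genes 1 fell (camera adjusted p = 0.00462, estimated adjusted p = 0.193). MHC class II genes moved down, with 0 of 9 passing (camera adjusted p = 0.00462, estimated adjusted p = 0.465). Lymphocyte and club or ciliated transcripts moved up beside them (camera adjusted p = 0.00462 and 0.047, adjusted p = 0.132 and 0.184 with an estimated correlation). The count of 435 was 272 and 232 without anti-IL6R HTO2 and HTO3.
The combination lowered Nrg1 (-2.55 ± 0.36), Eno1 (-1.19 ± 0.15) and Hopx (-1.07 ± 0.21) and raised the chemokine Ccl5 (2.33 ± 0.46). No lipid-associated gene passed (camera adjusted p = 2.77e-05 downward, estimated adjusted p = 0.086). Lymphocyte transcripts rose beside these genes (1 riser, 3 adjusted over the list alone, estimated adjusted p = 0.00572). The count of 173 was 110 without combination HTO3. Against anti-OSM the combination had lower Ccl24, an eosinophil attractant (-4.28 ± 0.89), Ier3 (-1.07 ± 0.21) and Socs3 (-0.72 ± 0.18; lost in 3 of 10 leave-one-out fits, highest adjusted p = 0.0813), with 3 of 14 gp130-STAT3 responsive genes falling (camera adjusted p = 9.13e-04, estimated adjusted p = 0.2). Stress genes fell in 4 of 16 (camera adjusted p = 1.52e-04, estimated adjusted p = 0.2), and the lymphocyte list with Ptprc moved up (camera adjusted p = 0.0457, estimated adjusted p = 0.2). The count of 347 was 171 and 193 without combination HTO3 and HTO4. Against anti-IL6R no MHC class II gene passed over all genes and 7 of 9 rose adjusted over the list alone (camera adjusted p = 7.38e-12, estimated adjusted p = 0.0453). The lymphocyte list with Ptprc moved up too (camera adjusted p = 0.0488, estimated adjusted p = 0.156). That count of 30 was 14 to 19 without any 1 of anti-IL6R HTO2, HTO3, HTO4 and HTO5 and combination HTO1 and HTO2.

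T-like cells after bleomycin with isotype had more regulatory T cell genes and fewer naive ones. Foxp3, the regulatory lineage factor, rose from 11.1 ± 3.89 to 86.9 ± 11.4 CPM (2.95 ± 0.21, adjusted p = 5.04e-12) and Ctla4, an inhibitory receptor, from 108 ± 11.7 to 552 ± 108 (2.34 ± 0.15, adjusted p = 2.74e-13). Of 10 regulatory genes 9 rose (camera adjusted p = 1.02e-12), a call that held with an estimated correlation (adjusted p = 0.00529). The risers included the repair factor Areg (3.54 ± 0.36), beside Itgb8, an integrin that activates TGF-beta (4.44 ± 0.42). Naive and memory genes fell in 7 of 10 (camera adjusted p = 4.18e-05, estimated adjusted p = 0.108), such as the homing receptor Ccr7 (-1.11 ± 0.17). Stat3 rose from 223 ± 36.5 to 489.9 ± 74.4 CPM (1.11 ± 0.12, adjusted p = 2.60e-08). Altogether 4 of 10 gp130-STAT3 responsive genes rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0752), while Socs3 did not pass (-0.05 ± 0.19, adjusted p = 0.906). Proliferation genes rose in 7 of 17 (11 adjusted over the list alone; camera adjusted p = 6.26e-05, estimated adjusted p = 0.222). Type 17 genes went both ways (3 up, 3 down of 11; camera adjusted p = 0.716), as did cytotoxic genes (1 up, 3 down of 11; camera adjusted p = 0.929), and no interferon gene passed. Stress genes rose in 9 and fell in 3 of 16 (camera adjusted p = 0.0198, estimated adjusted p = 0.108). Macrophage transcripts (2 of 3; camera adjusted p = 0.0198, estimated adjusted p = 0.102) and neutrophil ones fell beside these groups (3 of 3; camera adjusted p = 0.00213, estimated adjusted p = 0.108). Cluster 11 of the gate held 2.80% of the class with PBS and 23.7% with isotype.

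Anti-IL6R lowered gp130-STAT3 responsive genes in T-like cells. Socs3 fell from 57.4 ± 25 to 26.8 ± 2 CPM (-1.14 ± 0.19, adjusted p = 1.94e-04), Stat3 from 489.9 ± 74.4 to 282 ± 35.5 (-0.79 ± 0.11, adjusted p = 1.37e-05). Bcl3, a nuclear cofactor of NF-kappaB, fell from 57.8 ± 25.1 to 25.2 ± 8.17 (-1.19 ± 0.27; lost in 1 of 10 leave-one-out fits, highest adjusted p = 0.0554). Of 10 genes of the list 3 fell (4 adjusted over the list alone; camera adjusted p = 5.69e-04), and the call held with an estimated correlation (adjusted p = 0.01) and in all 10 leave-one-out fits (highest adjusted p = 0.0236 with an estimated correlation). Ctla4 fell by 0.50 ± 0.13 (lost in 3 of 10 leave-one-out fits, highest adjusted p = 0.0787) and was at 0.20 under another naming of clusters, and 1 of 10 regulatory genes fell (camera adjusted p = 0.015, estimated adjusted p = 0.516). Prf1, which encodes perforin, rose by 0.87 ± 0.19, with 2 of 11 cytotoxic genes rising (camera adjusted p = 0.015, estimated adjusted p = 0.601). Macrophage transcripts rose beside these groups (2 of 3; estimated adjusted p = 7.30e-04).
In the combination the same list moved: Socs3 stood at 26.6 ± 5.24 CPM (-1.15 ± 0.19, adjusted p = 1.85e-04), Stat3 fell by 0.68 ± 0.11 and the kinase Pim1 by -0.48 ± 0.09 (-0.29 and not called under another naming of clusters). Of 10 list genes 4 fell (5 adjusted over the list alone; camera adjusted p = 1.90e-04, estimated adjusted p = 0.00817). Itgb8 fell (-1.16 ± 0.25), with 2 of 10 regulatory genes (camera adjusted p = 0.009, estimated adjusted p = 0.285). The cytotoxic granule gene Nkg7 rose (0.80 ± 0.18), with 4 of 11 cytotoxic genes (camera adjusted p = 0.00169, estimated adjusted p = 0.285). Macrophage transcripts rose beside these (2 of 3; estimated adjusted p = 0.00973), and neutrophil ones in 2 cases (camera adjusted p = 0.00169, estimated adjusted p = 0.132).
With anti-OSM no gp130-STAT3 responsive gene passed (camera adjusted p = 0.788) and Socs3 stood at 52.4 ± 8.36 CPM against 57.4 ± 25 (-0.15 ± 0.18, adjusted p = 0.815). Regulatory and proliferation genes moved down with none passing (camera adjusted p = 6.97e-04 and 2.16e-05, estimated adjusted p = 0.51 and 0.573). In the test of the combination against anti-OSM, which compares the arms directly, Socs3 (-1.0 ± 0.19), Pim1 (-0.45 ± 0.09) and Stat3 (-0.50 ± 0.11) were lower, with 3 of 10 list genes (camera adjusted p = 4.57e-04, estimated adjusted p = 0.0126), and 1 of 3 macrophage transcripts higher (estimated adjusted p = 0.0198). Against anti-IL6R the combination left Socs3 unmoved within error (-0.01 ± 0.21, adjusted p = 1; list camera adjusted p = 0.646), while macrophage transcripts were lower and neutrophil ones higher (adjusted p = 0.0105 and 0.0123 with an estimated correlation). In GRCm38 with GENCODE M21 annotation Socs3 lies on chromosome 11, 117966079 to 117970047, Stat3 on chromosome 11, 100885098 to 100939540, Pim1 on chromosome 17, 29490753 to 29496112 and Bcl3 on chromosome 7, 19808462 to 19822770. Spp1 lies on chromosome 5, 104435118 to 104441050, and Acta2 on chromosome 19, 34241090 to 34255590. Cthrc1 lies on chromosome 15, 39076932 to 39087121, and Lcn2 on chromosome 2, 32384633 to 32388252.

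**Figure D4:**
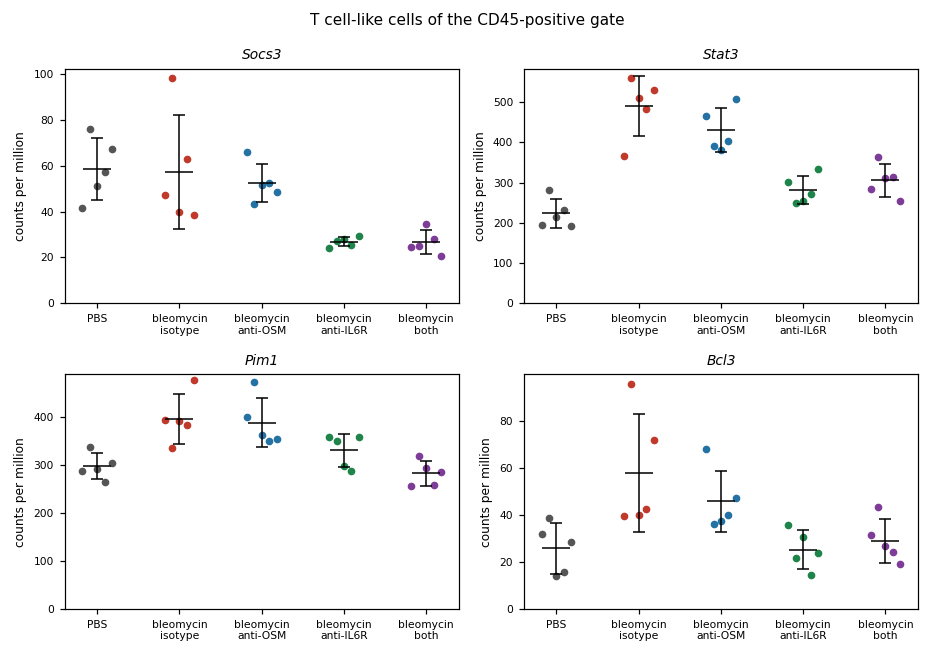
Points are the expression (y axis, CPM) of Socs3, Stat3, Pim1 and Bcl3 in T-like cells of each of 5 hashtag subsets per arm (x axis), with mean and SD. Mean Socs3 was 57.4 CPM with isotype, 52.4 with anti-OSM, 26.8 with anti-IL6R and 26.6 with the combination.

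Genes that bleomycin had raised tended to fall with antibody, and the reverse. In fibroblast-like cells 1796 genes were called in opposite directions by bleomycin and by anti-IL6R, against 591 for independent lists, and 57 in the same direction. For anti-OSM the numbers were 795, 255 and 39, and for the combination 510, 207 and 42. Both contrasts share the isotype subsets and library, which alone gives a negative relation. The simulations given here hold only the spread between subsets, so they cannot test a shift of the isotype library. Across genes, which are not independent replicates, the covariance of the fold changes was -0.147 for anti-OSM, -0.181 for anti-IL6R and -0.105 for the combination, against -0.0232, -0.0233 and -0.0233 in simulations of unchanged groups. In AT2-like cells 922 genes were opposite with anti-IL6R and 1127 with the combination (233 and 290 for independent lists), in capillary endothelial-like cells 891 and 610 (334 and 239). In monocyte-derived macrophage-like cells they were 213 and 110 (64.2 and 25.5) and in T-like cells 299 and 250 (47.9 and 45.4). Pairs of antibody arms share the isotype subsets and library too, which alone gives a positive relation. Anti-IL6R and the combination moved the same genes: 775 in fibroblast-like cells in the same direction (100 for independent lists) and 0 opposite, 857 in AT2-like, 1507 in capillary endothelial-like, 122 in monocyte-derived macrophage-like and 274 in T-like cells. The covariance of their fold changes was 0.0954, 0.153, 0.121, 0.0951 and 0.0758 in that order of classes, against 0.0232, 0.0350, 0.0184, 0.0301 and 0.0248 in simulations of unchanged groups. Anti-OSM and anti-IL6R shared 751 genes of the same direction in fibroblast-like cells (covariance 0.102, against 0.0230 for unchanged groups) and 6 in monocyte-derived macrophage-like cells (0.0279 against 0.0303).

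Some genes moved alike in unrelated cells. With anti-IL6R 102 genes were called in the same direction in classes of all 3 gates, 57 up and 45 down, 22 of them in all 5 classes. Cirbp, Rbm3 and the ribosomal gene Rplp0 were lower in each class, and Lrp1b, Sema3c and the chaperone partner Fkbp4 higher. For the combination there were 54 such genes, for anti-OSM 1 and for bleomycin with isotype against PBS 730.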

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

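Of the tests in this part, those between fibroblast-like cells of 2 gates, paired or not, the interval for transcript length and the 30 counts of other splits were chosen only after the result was seen.

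In 13 of 140 groups of share values 1 hashtag subset lay far from the other 4, where chance gives about 1 in 20 groups. Neutrophil-like cells accounted for 4: HTO2 held 25.3% of CD45-positive cells with PBS (others 6.84 to 7.88%), 13.3% with isotype (3.49 to 5.51%) and 0.538% of triple-negative cells with PBS (0.122 to 0.239%), and HTO1 11.6% of CD45-positive cells with the combination (4.85 to 5.68%). Isotype HTO2 was also low in NK-like cells (1.33%, others 3.84 to 4.21%) and high in ciliated-like cells (9.10%, others 1.72 to 2.66%). Alveolar macrophage-like cells made up 11.7% in PBS HTO5 (5.62 to 7.27%) and 1.46% in anti-OSM HTO2 (0.0857 to 0.450%), which was high in AT1-like cells too (3.32%, others 1.07 to 1.61%). The remaining subsets were anti-OSM HTO5 for plasmacytoid dendritic-like (0.428%), anti-IL6R HTO1 for ciliated-like (1.72%), anti-IL6R HTO3 for venous endothelial-like (3.83%) and PBS HTO1 for fibroblast-like cells of the CD31/EpCAM gate (14.8%, others 20.5 to 20.8%).

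Among the 6 pathway genes, 12 of 110 groups had such a subset. In fibroblast-like cells anti-IL6R HTO5 was high for Il6 (590.6 CPM, others 363 to 427), Il6ra (44.6) and Osmr (221), and anti-OSM HTO2 for Il6ra (46.8) and Socs3 (709, others 266 to 384). Il6 stood at 52.2 CPM in AT2-like cells of isotype HTO3 and 67.6 in macrophage-like cells of PBS HTO3 (others 0 to 8.82). Il6st was 306 and 296 CPM in capillary endothelial-like cells of PBS HTO1 and anti-OSM HTO1, and Socs3 370 there in combination HTO5 (others 513 to 559). Il6ra was 181 CPM in macrophage-like cells of combination HTO1 and 189 in T-like cells of PBS HTO1.

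Fibroblast-like cells occurred in 2 gates, and a test of the difference between gates found genes that responded differently: 499 for bleomycin with isotype, 323 for anti-OSM, 995 for anti-IL6R, 266 for the combination, 804 for the combination against anti-OSM and 121 against anti-IL6R, of 14367 tested. With paired subsets the counts were 1307, 1123, 2264, 778, 2138 and 476. In 3 unnamed clusters, outside all comparisons, every isotype subset had a larger share than any PBS subset: CD31/EpCAM 7, with Krt8 and Sftpc (9.39 against 0.265%), CD31/EpCAM 28 (0.313 against 0.0707%) and triple-negative 28, with the platelet genes Pf4 and Ppbp (0.837 against 0.0628%).

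More genes changed with anti-IL6R than with anti-OSM against isotype, in fibroblast-like cells 2919 against 1257. After thinning every subset to equal UMIs the ratio of the counts was still 2.40, over the bound of 1.5 set beforehand, which argues against a difference in depth. A library batch stays open. Of genes called in 1 class, a median of 67.4% kept their sign in a class of another gate (90% set for a batch, 60% against). Gates are separate libraries, so this cannot test a batch within a library, and isotype against PBS gave 64.1%. Batch and antibody cannot be told apart. That blocking IL6R reaches more cells or genes than blocking OSM also stays open, untested.

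With anti-IL6R 102 genes changed alike in classes of all 3 gates. Transcript length stays open: the fallers' median exonic length was 0.695 of the risers' (2702 against 3890 bases), within the factor of 1.5 set beforehand against it, but with genes redrawn the 95% interval was 0.558 to 1.15, which reaches past that bound and not to the 0.5 set for it. Gene spans were 6969 against 12659 bases. Of the 102 genes 27.5% differed between the isotype libraries of 2 gates in fibroblast-like cells, against 19.0% of all genes (41.2 and 26.9% with paired subsets). This lies between the bounds for and against a library effect, so that library and antibody cannot be told apart here. A response of all cells to IL6R antibody stays open, untested.

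Other splits of the 10 subsets of 2 arms were refitted for all 30 counts (40 of 126 drawn). In each only 1 of 40, the real one, called as many genes. Chance is less likely but not excluded, and some margins below were thin. A library difference, which follows the real split, stays open. The order of comparisons is isotype against PBS, anti-OSM, anti-IL6R and the combination against isotype, and the combination against anti-OSM and against anti-IL6R. In fibroblast-like cells the real count and the highest of the others were 6051 and 2776, 1257 and 906, 2919 and 619, 1023 and 243, 1260 and 2 and 59 and 1. For AT2-like cells they were 3438 and 649, 52 and 43, 1170 and 36, 1458 and 851, 445 and 26 and 33 and 1. For capillary endothelial-like cells they were 2810 and 434, 252 and 66, 2718 and 658, 1943 and 441, 1399 and 78 and 194 and 18. For macrophage-like cells they were 2681 and 416, 61 and 8, 435 and 19, 173 and 2, 347 and 13 and 30 and 1. For T-like cells they were 2013 and 606, 124 and 2, 473 and 13, 449 and 19, 393 and 81 and 44 and 0.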

How the results depend on the processing

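Of the alternatives below, those chosen only after the data were seen were the naming of clusters against the rest of their gate, the fits without clusters of few UMIs, without genes alike in all 3 gates and with thinned subsets, the fibroblast-like cells of the CD31/EpCAM gate, leaving out subsets in the list and share tests, and the split of the isotype subsets for the overlap. Comparisons are named by their first arm, which stood against isotype (for isotype, against PBS), unless a second arm is given. All values rest on 5 hashtag subsets per arm, a single 10x library per arm and gate, and 325987 to 12715537 UMIs per subset and class. On simulated data at these depths, a 2-fold change was called for 64.2 to 85.2% of genes, and a 1.5-fold change for 21% in macrophage-like and 60.3% in capillary endothelial-like cells, so small changes in macrophage-like cells were often not detectable. No paired analysis was possible between arms because the labels do not link a hashtag number across arms to 1 animal. Between the 2 gates of an arm, where numbers pair the subsets, a replicate block, chosen after the data were seen, raised all 6 counts of genes whose change differed between gates (1307, 1123, 2264, 778, 2138 and 476, each over 1.5 times) and kept the genes called between isotype gates within 1.5 times.

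Of the 30 counts of called genes, all 30 stayed within 1.5 times with relative log expression normalization, with the stricter hashtag call and without genes alike in all 3 gates. With DESeq2 25 did, with no low-count filter 17, with only the 2 compared arms fitted 20 and after thinning 8. Among 786 called named genes, relative log expression normalization ended 3 calls, the stricter hashtag call 13, no filter 11, DESeq2 32 (of 776), fitting the 2 arms alone 110 (of 762), and leaving out a subset 975 of 7860. For every change below the cause was not tested, except that fits of 2 arms rest on fewer subsets and thinning leaves fewer genes to test.

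With DESeq2 the counts that moved were all higher. Fibroblast-like cells had 195 with the combination against anti-IL6R. AT2-like cells had 112 with anti-OSM. Macrophage-like cells had 200 with anti-OSM, 276 with the combination and 78 with the combination against anti-IL6R. With no low-count filter 12 counts were higher and 1 lower. Fibroblast-like cells had 658 with the combination. AT2-like cells had 224 with anti-OSM and 127 with the combination against anti-IL6R. Capillary endothelial-like cells had 393 with anti-OSM and 304 with the combination against anti-IL6R. Macrophage-like cells had 409 with anti-OSM, 749 with anti-IL6R, 579 with the combination, 635 with the combination against anti-OSM and 194 with the combination against anti-IL6R. T-like cells had 301 with anti-OSM, 599 with the combination against anti-OSM and 93 with the combination against anti-IL6R. With only the 2 compared arms fitted 9 counts were lower and 1 higher. Fibroblast-like cells had 243 with anti-OSM, 536 with the combination and 595 with the combination against anti-OSM. AT2-like cells had 16 with anti-OSM and 68 with the combination against anti-OSM. Capillary endothelial-like cells had 154 with anti-OSM. Macrophage-like cells had 1 with anti-OSM, 125 with the combination against anti-OSM and 48 with the combination against anti-IL6R. T-like cells had 43 with anti-OSM. Thinning to equal UMIs lowered 22. Fibroblast-like cells had 792 with anti-OSM, 1898 with anti-IL6R, 570 with the combination, 807 with the combination against anti-OSM and 12 with the combination against anti-IL6R. AT2-like cells had 1690 with isotype, 648 with anti-IL6R, 598 with the combination, 255 with the combination against anti-OSM and 19 with the combination against anti-IL6R. Macrophage-like cells had 1660 with isotype, 25 with anti-OSM, 112 with anti-IL6R, 44 with the combination, 146 with the combination against anti-OSM and 11 with the combination against anti-IL6R. T-like cells had 795 with isotype, 43 with anti-OSM, 158 with anti-IL6R, 140 with the combination, 144 with the combination against anti-OSM and 5 with the combination against anti-IL6R.

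Leaving out 1 subset gave ranges of counts that crossed the 1.5-fold limit. Fibroblast-like cells ranged from 702 to 1496 with anti-OSM, 627 to 1087 with the combination, 797 to 1337 with the combination against anti-OSM and 6 to 72 with the combination against anti-IL6R. AT2-like cells ranged from 821 to 1697 with the combination and 285 to 864 with the combination against anti-OSM. Macrophage-like cells ranged from 13 to 102 with anti-OSM, 232 to 396 with anti-IL6R, 110 to 156 with the combination, 171 to 350 with the combination against anti-OSM and 14 to 38 with the combination against anti-IL6R. Among named genes Igkc, a B cell transcript, ranged from -2.73 to 0.86 in T-like cells with isotype, and Scgb3a2, a club cell transcript, turned to 0.52 in capillary endothelial-like cells with the combination, without isotype HTO4.

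Naming clusters against the rest of their gate kept 14 of 24 counts within 1.5 times. Fibroblast-like cells had 26 with the combination against anti-IL6R. AT2-like cells had 90 with anti-OSM, 761 with anti-IL6R, 947 with the combination and 129 with the combination against anti-OSM. Capillary endothelial-like cells had 142 with anti-OSM, 943 with the combination, 807 with the combination against anti-OSM and 108 with the combination against anti-IL6R. T-like cells had 1226 with isotype. Signs turned for Sprr1a (1.49) in AT2-like cells with the combination, Cryab (0.057) in AT2-like cells with the combination against anti-OSM, Car4 (0.38), Emp2 (0.38), Fibin (0.21) and Kdr (0.44) in capillary endothelial-like cells with isotype, Kit (0.041) in capillary endothelial-like cells with anti-IL6R, Pim1 (-0.17) in T-like cells with isotype, Ctla4 (0.20) in T-like cells with anti-IL6R and Ctla4 (0.17) in T-like cells with the combination. Without clusters of few UMIs, 8 of 12 counts stayed within 1.5 times, and AT2-like cells gave the same values as under that naming for both the 4 counts (90, 761, 947 and 129) and for Sprr1a (1.49) and Cryab (0.057).

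Fibroblast-like cells of the CD31/EpCAM gate kept 4 of 6 counts within 1.5 times and gave 250 with anti-OSM and 167 with the combination against anti-IL6R. Of 179 named genes called in the triple-negative gate, 84 were called alike there, 69 lost the call and 26 had the other sign. These 26, and 8 called there with the other sign only, follow. With isotype log2 fold changes there were Cntfr 0.65, Lyz2 -2.76 and Scgb3a2 3.10. For anti-OSM they were mt-Nd3 -1.96, Ereg 0.34, Steap4 -0.011, Hspa1b -0.62, Col12a1 0.060, Tpm1 0.043, Limch1 0.028 and Il11 0.87. For anti-IL6R they were mt-Nd3 -2.17, Zfp36 -0.11, Ier2 -0.19, Tnc 0.065, Ccl11 -0.24, Sftpa1 1.32 and Lyz2 1.23. For the combination they were mt-Nd3 -0.39, Pcna 0.29, Sftpa1 1.41, Lyz2 1.32 and Scgb1a1 0.15. For the combination against anti-OSM they were Serpine2 -0.35, Sntg1 0.30, Steap4 0.23, Il6st 0.18, Ier3 -0.32, Tnc -0.32, Tpm1 -0.43 and Lyz2 0.98. For the combination against anti-IL6R they read 2610307P16Rik -0.19, Wnt2 -0.064 and Lif -0.19.

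Lists called by camera numbered 96 of 366 with the preset correlation and 21 of these with an estimated one. Most of the 21, and all in capillary endothelial-like cells, were lists of transcripts of other cells, counting the lymphocyte list with Ptprc in macrophage-like cells. Fibroblast-like cells kept 0. AT2-like cells kept 1 with the combination against anti-IL6R and 0 otherwise. Capillary endothelial-like cells kept 2 with anti-OSM and with anti-IL6R and 1 with every other comparison. Macrophage-like cells kept 1 with isotype, the combination and the combination against anti-IL6R and 0 otherwise. T-like cells kept 0 with anti-OSM, 1 with isotype and 2 with every other comparison. With the estimated correlation 48 of all tests had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 78. Without 1 subset, at the preset correlation, the numbers of lists called crossed the 1.5-fold limit as follows. Fibroblast-like cells ranged from 2 to 4 with anti-OSM, 2 to 5 with anti-IL6R, 0 to 4 with the combination and 0 to 3 with the combination against anti-OSM. AT2-like cells ranged from 1 to 3 with anti-OSM, 1 to 3 with anti-IL6R, 0 to 1 with the combination, 0 to 1 with the combination against anti-OSM and 1 to 5 with the combination against anti-IL6R. Capillary endothelial-like cells ranged from 3 to 6 with anti-OSM, 1 to 2 with the combination and 1 to 3 with the combination against anti-IL6R. Macrophage-like cells ranged from 3 to 6 with anti-OSM, 2 to 4 with anti-IL6R, 2 to 4 with the combination and 3 to 7 with the combination against anti-IL6R. T-like cells ranged from 2 to 5 with anti-OSM and 2 to 5 with the combination against anti-IL6R.

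The number of classes whose share passed the exact permutation test was 0 with isotype in the triple-negative gate under both the filter of 1000 genes and 10% mitochondrial UMIs and the stricter hashtag call (2 and 3 classes at an unadjusted p under 0.05), while the other share counts of these settings and all at Leiden resolution 2.0 stayed within 1.5 times. Without 1 subset they ranged from 0 to 5 in the triple-negative gate with isotype, 0 to 3 in the triple-negative gate with the combination, 2 to 5 in the CD31/EpCAM gate with isotype and 5 to 8 in the CD45-positive gate with isotype. At these 2 counts of 0 there were at least 2 and 1 classes at an unadjusted p under 0.05.

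Using one part of the isotype subsets for bleomycin and the other for antibody brought the correlation across genes between the fold changes of bleomycin and of antibody nearer 0. Both parts came from the same isotype library, so the split cannot remove a shift of that library. Fibroblast-like cells had -0.46 for anti-OSM and -0.54 for anti-IL6R. AT2-like cells had -0.19 for anti-OSM, -0.49 for anti-IL6R and -0.46 for the combination. Macrophage-like cells had -0.29 for anti-OSM, -0.21 for anti-IL6R and -0.31 for the combination. T-like cells had -0.25 for anti-OSM, -0.29 for anti-IL6R and -0.24 for the combination. For the overlap of pairs of antibody arms, split in the same way, correlations fell too. Fibroblast-like cells had 0.45 for anti-OSM and anti-IL6R, 0.28 for anti-OSM and the combination and 0.49 for anti-IL6R and the combination. AT2-like cells had 0.13 for anti-OSM and anti-IL6R, 0.13 for anti-OSM and the combination and 0.50 for anti-IL6R and the combination. Capillary endothelial-like cells had 0.27 for anti-OSM and anti-IL6R, 0.14 for anti-OSM and the combination and 0.58 for anti-IL6R and the combination. Macrophage-like cells had -0.039 for anti-OSM and anti-IL6R, 0.087 for anti-OSM and the combination and 0.37 for anti-IL6R and the combination. T-like cells had 0.087 for anti-OSM and anti-IL6R, 0.10 for anti-OSM and the combination and 0.39 for anti-IL6R and the combination. The value of macrophage-like cells for anti-OSM and anti-IL6R turned negative, and the cause was not tested.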

Other observations

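The 12 unnamed clusters entered no test. Their mean shares of the gate follow in the order PBS, isotype, anti-OSM, anti-IL6R and combination. In the CD31/EpCAM gate cluster 7, which expressed Krt8, Sftpc and Ager together, made up 0.265, 9.39, 3.70, 3.46 and 6.41%, and cluster 29, with Calca, 0.0398, 0.462, 0.138, 0.118 and 0.189%. Cluster 14, with Vwf, made up 2.05, 1.99, 2.18, 1.59 and 1.76%, and cluster 28 0.0707, 0.313, 0.261, 0.0948 and 0.225%. In the triple-negative gate the platelet-like cluster 28 made up 0.0628, 0.837, 0.719, 0.127 and 0.115%, and cluster 2, with Aspn, Hhip and Acta2, 6.46, 8.62, 6.44, 6.96 and 8.23%. The cardiac muscle-like cluster 21 held 0.817, 0.855, 0.957, 0.670 and 0.800%, the pericyte-like cluster 25 0.411, 0.564, 0.904, 0.359 and 0.520%, and cluster 30 0.0664, 0.122, 0.219, 0.00979 and 0.0696%. Among CD45-positive cells cluster 7, with Il1b and Ccl17, held 2.76, 3.78, 3.43, 4.72 and 4.44%, the monocyte-like cluster 17 2.69, 2.19, 1.54, 3.12 and 2.78%, and cluster 28 0.501, 0.111, 0.345, 0.442 and 0.254%.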
